A study of Arabidopsis thaliana with 4 samples.

How the data were processed

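Total RNA from mixed-stage inflorescences was hybridized to 4 Affymetrix ATH1 arrays, 2 for Col-0 and 2 for xrn4-5. Plants grew with 16 h of light and 8 h of dark at 21 °C, and biotin-labelled RNA was made from 15 µg of total RNA, per the labels' protocols. GCOS is named in the submitters' processing notes, with no version given.

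The deposited value table holds 1 intensity per probe set and array, on a linear scale. The 2% trimmed mean over all probe sets was 500.04 in each of the 4 arrays, so the values had been scaled together before they were deposited. The authors also deposited a table of their own comparisons, which gives a log2 ratio of xrn4-5 over Col-0 for each pair of same-numbered arrays, rounded to 1 decimal, per the file headers and its values. In it the authors give a change p-value per probe set and pair, near 0 for an increase and near 1 for a decrease. How it was computed is not given in the sources used here, and it was used only as the authors' own comparison.

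Intensities were analysed as log2(value + 32) with no further normalization. Fold changes are on this scale, which understates the change of dim probe sets. The 64 control probe sets were left out of the tests, as were the 40% of probe sets with the lowest mean over all 4 arrays, which left 13647. Differences were tested two-sided with lmFit and eBayes(trend=TRUE) of limma 3.58.1 in R 4.3.3, with 2 residual degrees of freedom per probe set and a prior of 3.73, and Benjamini-Hochberg adjustment at 0.05. Means ± SD are of linear intensities. Gene lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Arrays of a genotype were no duplicates of each other: 47 of 22810 values were identical between the xrn4-5 arrays and 46 between the Col-0 arrays.

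The tests were tried on simulated data, with 13647 probe sets, 200 of them changed, and the means and variance prior of this comparison. Over 20 simulations the adjusted test recovered 47.5% of the 2-fold, 94.3% of the 4-fold and 99.2% of the 8-fold changes, with a mean of 8 false calls. The second criterion recovered 50.1% of the 2-fold changes, with a mean of 37 false calls. At an unadjusted p under 0.05, camera called 20 of 20 sets of 10 genes raised by 0.35 on the log2 scale. It called 1 of 20 unchanged ones. The simulation has no spread shared between probe sets, and in that it is more favourable than real arrays. It also has none shared between same-numbered arrays, whose deviations correlated at 0.42 over tested probe sets. Its counts of false calls need not hold here.

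Genes were named from the platform annotation, updated through gene identifiers to the TAIR10.1 names. Without controls, 13513 probe sets have 1 gene there, 503 have several and 8730 are not listed, and those not listed are unnamed here. Of the probe sets with 1 gene, 13436 matched the reference. Only 78 of the 492 list entries had a named probe set and 50 were tested, so the lists describe a small part of each pathway. For a gene with several probe sets, the one with the highest mean was used.

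The rule for named genes was fixed before the data were examined. It took XRN4, then per direction up to 12 probe sets with the largest difference among those with an adjusted p under 0.05, exactly 1 named gene and separated arrays. Where fewer than 12 passed, up to 6 with the smallest unadjusted p followed. It further took up to 4 members of each list with the smallest p, EBF1 and EBF2, and the control probe sets for the parts of a transcript. The lists, the tests and most alternatives were fixed at the same time.

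There were 2 departures from that plan. The plan searched 46 gene family patterns in gene descriptions and was not to be run without them. No descriptions were given, so the search was run, after the data had been seen, on gene symbols and their synonyms, which spell out some names. This left 8 families with 10 or more tested genes, and their results are not those of a planned test. A test of the 4096 hexamers in transcript sequences was not run, because no transcript sequences were used here. Alternatives changed the pseudocount, the filter on dim probe sets, the normalization, the variance prior, the array number as a block, the arrays used, the test per probe set and the correlation between genes.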

Results

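Transcript levels were measured in mixed-stage inflorescences of Arabidopsis thaliana with the ATH1 oligonucleotide array. Col-0 plants, the wild type, were compared with plants carrying xrn4-5, an allele of XRN4. XRN4 is a cytoplasmic exoribonuclease that degrades uncapped RNA from its 5' end. Each genotype was represented by 2 arrays, numbered 1 and 2, so 4 arrays were analysed. The comparison asks which transcripts differ in level when XRN4 function is altered. The median signal per array lay between 240 and 248, and each array carried 22810 probe sets. With only 2 arrays per genotype, the number of arrays limits the precision of every value. The sources used here do not state whether the 2 samples of a genotype came from separately grown plants, so p-values measure only the spread between these samples, which may be technical.

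The mutated gene itself could not be followed as a check of the labels, because no probe set is named for XRN4 in the annotation used here. The same holds for EBF1 and EBF2, F-box genes of the ethylene pathway whose transcripts are known to accumulate in xrn4 mutants. Their levels were not analysed here.

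One probe set rose in xrn4-5. The signal of 251109_at, which has no named gene here, averaged 5271 ± 613 (SD, n = 2) in xrn4-5 and 824 ± 64.6 (SD, n = 2) in Col-0. The difference was 6.19-fold, with a 95% interval from 4.91 to 7.80, and limma gave an adjusted p of 0.0256. In the authors' deposited table, its log2 ratios were 2.4 and 2.8 in the 2 pairs. This single call ended when dim probe sets were kept, when the variance prior had no trend, with a test that shares no variance between probe sets, and when either xrn4-5 array was left out. No probe set passed the limma test without a block as lower in xrn4-5. With the array number as a block, 131 probe sets passed in either direction, 251109_at included. The labels do not say that a number marks a shared batch. At an unadjusted limma p under 0.05 without a block, 1273 of 13647 probe sets differed, 734 higher and 539 lower.

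Among probe sets with exactly 1 named gene, those with the smallest p differed by about 2-fold, and all of them missed the test without a block. With the array number as a block, all 12 of these genes, given here and in the next paragraph, passed. Some unnamed probe sets came nearer to the threshold. AT2G25250 gave signals of 1030 and 1003 in the xrn4-5 arrays against 393 and 377 in the Col-0 arrays, 2.51-fold higher (limma adjusted p = 0.132). AT4G32020 averaged 3989 ± 255 (SD, n = 2) against 1712 ± 146, 2.31-fold higher (limma adjusted p = 0.159). AT1G68490 averaged 3532 ± 366 against 1296 ± 274, and AT1G30200 averaged 828 ± 23.0 against 401 ± 4.10. EXPA15, which encodes an expansin, a protein that loosens cell walls, averaged 2483 ± 78.2 against 1290 ± 63.6. For AT1G04660 the means were 410 ± 42.8 and 175 ± 3.54. These last 4 genes had limma adjusted p-values from 0.238 to 0.290.

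In the opposite direction, AT4G21870 had a signal of 231 ± 17.2 (SD, n = 2) in xrn4-5 and 581 ± 47.6 in Col-0, 2.32-fold higher in Col-0 (limma adjusted p = 0.217). AT2G45180 averaged 1434 ± 142 against 3050 ± 176, 2.11-fold higher in Col-0 (limma adjusted p = 0.238). AT1G23570 averaged 757 ± 32.1 against 1455 ± 17.7. The means of AT2G47050 were 2164 ± 8.27 and 3828 ± 509, those of AT5G61720 were 1447 ± 16.8 and 2523 ± 285, and those of AT1G28375 were 913 ± 1.70 and 1610 ± 185. The last 4 genes had limma adjusted p-values from 0.250 to 0.377.

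A second, less strict criterion asked for an unadjusted limma p under 0.05, a difference of at least 2-fold and both xrn4-5 arrays on the same side of both Col-0 arrays. It was met by 25 probe sets with higher and 31 with lower signal in xrn4-5. In simulated data with 200 changed probe sets, a mean of 37 unchanged probe sets met this criterion. The simulated arrays were independent, unlike same-numbered arrays here, so 37 need not hold. Across genotype and number, array 1 of xrn4-5 and array 2 of Col-0 against the others, 7 probe sets met it. Differences of genotype and number fall within those groups, so 7 is no count of false ones either. With the array number as a block, 48 of the 56 passed the adjusted limma test. How many of the 56 are false is not known, so they are not 56 established differences. Leaving out array 2 of Col-0 gave 98 and 72, and leaving out array 1 of Col-0 gave 36 and 86. Only 9 of the 25 and 12 of the 31 have exactly 1 named gene. Those not named above are given here after their values were seen. Every one of them missed the limma test without a block (adjusted p from 0.330 to 0.518).

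Among the higher genes, SAPX, the ascorbate peroxidase of the chloroplast stroma, averaged 1380 ± 429 (SD, n = 2) in xrn4-5 against 558 ± 126 in Col-0. AT2G36885 averaged 1652 ± 300 against 758 ± 334, and AT3G53980 averaged 894 ± 253 against 395 ± 155. AT1G20070 averaged 599 ± 90.7 against 261 ± 29.1. AT1G01250, of the AP2/ERF family of transcription factors, averaged 1235 ± 365 against 561 ± 124.

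Among the lower genes, the widest gaps belonged to AT1G47400 and AT5G05250. AT1G47400 gave signals of 2335 and 290 in the xrn4-5 arrays against 7418 and 6770 in the Col-0 arrays, a log2 difference of -3.03. AT5G05250 gave 419 and 104 against 1853 and 1582, a log2 difference of -2.81. In both genes the xrn4-5 arrays differed several-fold from each other. AT3G56360 averaged 2144 ± 1163 (SD, n = 2) in xrn4-5 against 5170 ± 707 in Col-0. PYE, a basic helix-loop-helix regulator of the root response to iron deficiency, averaged 272 ± 67.7 against 609 ± 195. EXO, a gene induced by brassinosteroids, averaged 469 ± 102 against 1074 ± 321. The plastid gene ndhF, encoding a subunit of the chloroplast NADH dehydrogenase-like complex, averaged 231 ± 26.9 against 554 ± 283. AT1G44830, AT1G49500, AT3G19030 and AT1G55450 lay between 2.07-fold and 2.38-fold higher in Col-0.

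**Figure D1:**
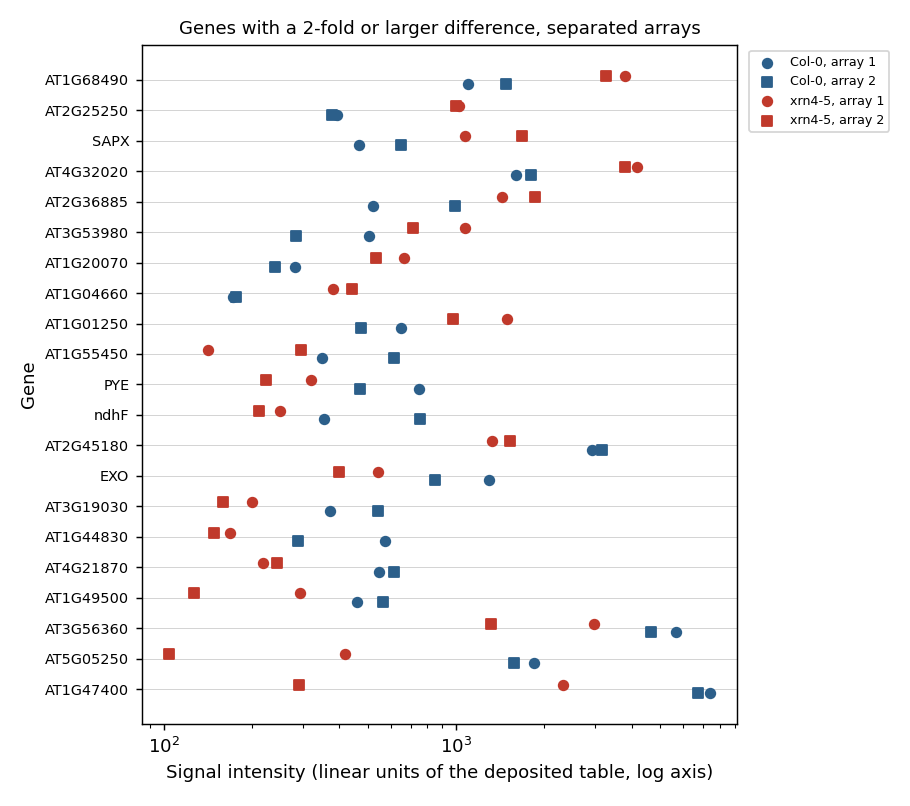
Signal intensity of the 21 genes that met the less strict criterion, on a log axis, with 1 point per array (red, xrn4-5; blue, Col-0; circles, array 1; squares, array 2). AT1G68490 has the largest log2 difference among the higher genes, 1.44, and AT1G47400 the largest among the lower ones, -3.03.

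The authors' deposited table compares the same-numbered arrays pair by pair. In the authors' deposited table, 209 of 22746 probe sets, dim ones included, were at least 2-fold higher in xrn4-5 in both pairs. At least 2-fold lower in both were 196, while 302 differed 2-fold in opposite directions in the 2 pairs. If the pairs were independent, 42.4 would be higher in both, 45.5 lower in both and 88.3 opposite. The opposite count also exceeded its value, so an excess over independent pairs is no measure of a difference between the genotypes. With a change p-value under 0.01 in both pairs as well, 26 were higher, and with one over 0.99 in both, 36 were lower in the authors' deposited table. AT1G47400 had log2 ratios of -1.6 and -4.6 in the 2 pairs of the authors' deposited table, and AT2G25250 had 1.6 and 1.2.

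Of the 19 gene lists fixed before the data were examined, 16 had at least 1 tested member and 8 had 3 or more. None passed camera at an adjusted p under 0.05 with all 4 arrays and no block. With the array number as a block, 1 did (abscisic acid and dehydration, camera adjusted p = 0.0202). Without array 2 of Col-0, camera called 3 lists (abscisic acid and dehydration, clock, seed and embryo), and without array 1 of Col-0 it called 1 (rapid stress and touch). With an unadjusted p under 0.05 camera gave 1 list and fry gave 1 list, and no list passed after adjustment with an estimated correlation or with fry. No member of any list passed the limma test over all probe sets. Adjusted over the list alone, 1 member passed in the auxin list. The only tested clock gene had an unadjusted limma p under 0.05, which adjustment over its list leaves unchanged.

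RNA decay factors were the best covered group, with 11 tested members. The estimate was higher in xrn4-5 for 8 of them and lower for 3, and none passed either over all probe sets or adjusted over the list alone. LSM1B, of the ring complex that activates decapping, averaged 502 ± 60.7 (SD, n = 2) in xrn4-5 against 355 ± 8.56 in Col-0 (limma adjusted p = 0.456). The helicase gene AT3G61240 averaged 1352 ± 5.02 against 1065 ± 72.2. UPF3, of nonsense-mediated decay, averaged 758 ± 79.9 against 599 ± 14.6. RRP41, a subunit of the exosome, averaged 431 ± 47.4 against 561 ± 17.0. The camera adjusted p of the list was 0.582, and fry gave an unadjusted p of 0.0475 and an adjusted p of 0.616. In the RNA silencing list AGO7 averaged 275 ± 60.6 against 238 ± 5.66, and SE averaged 324 ± 56.6 against 344 ± 7.35.

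Targets of microRNAs had 6 tested members, 2 with a higher and 4 with a lower estimate, and none passed (camera adjusted p = 0.582). ARPN, a plantacyanin, averaged 1371 ± 114 (SD, n = 2) in xrn4-5 against 2251 ± 713 in Col-0. CCS, the copper chaperone of superoxide dismutase, averaged 405 ± 111 against 576 ± 193. APS4 averaged 694 ± 106 against 564 ± 52.1, and PHV, a leaf polarity factor, averaged 644 ± 116 against 533 ± 39.3.

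Hormone and stress lists held few measured genes. GH3.3, which conjugates auxin to amino acids, averaged 356 ± 31.0 (SD, n = 2) in xrn4-5 against 538 ± 30.0 in Col-0. Its limma adjusted p was 0.391 over all probe sets and 0.0125 adjusted over the list alone, whose only other tested member, WES1, averaged 909 ± 58.5 against 805 ± 256. In the ethylene list EIN3 averaged 1601 ± 124 against 1502 ± 90.2, and RTE1 averaged 513 ± 42.8 against 455 ± 28.6. The jasmonate gene JMT averaged 585 ± 100 against 588 ± 66.4. Of the genes induced by abscisic acid and dehydration, COR15A averaged 5693 ± 827 against 3600 ± 1666, COR47 averaged 4697 ± 175 against 4200 ± 248, and COR15B gave 794 and 2540 against 438 and 1997 in arrays 1 and 2. That list had a camera adjusted p of 0.309, and of 0.0202 with the array number as a block. STZ averaged 166 ± 67.2 against 356 ± 255, and WRKY53 averaged 185 ± 10.3 against 217 ± 110. Their list, rapid stress and touch, had a camera adjusted p of 0.517, and of 0.00247 without array 1 of Col-0. The clock gene GI averaged 484 ± 74.7 against 287 ± 103 (limma unadjusted p = 0.0286, adjusted p = 0.495 over all probe sets). As the only tested clock gene it had no other member to adjust over, and its list had a camera adjusted p of 0.309.

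Markers of the cell types in an inflorescence also stayed short of the threshold. All 4 tested genes of the tapetum list had lower estimates in xrn4-5 (camera unadjusted p = 0.0300, adjusted p = 0.309; adjusted p = 0.799 with an estimated correlation), although that of AT5G07230 came to 0.00 when array 2 of Col-0 was left out. The tapetal gene ATA27 averaged 5370 ± 191 (SD, n = 2) against 6163 ± 450, AT5G07230 averaged 2012 ± 279 against 2335 ± 471, AMS averaged 474 ± 66.7 against 528 ± 1.98, and AT1G06170 averaged 158 ± 3.54 against 192 ± 39.7. For late pollen, TUA1 averaged 778 ± 25.5 against 964 ± 160, ACT12 averaged 182 ± 2.33 against 232 ± 49.3, and AGL65 averaged 163 ± 4.60 against 172 ± 31.3. The floral genes AGL24 (193 ± 3.54 against 185 ± 25.8) and SPT (223 ± 0.424 against 219 ± 74.3) and the seed coat gene BAN (364 ± 64.1 against 426 ± 345) had log2 differences under 0.1. As the only tested seed gene, BAN had a camera adjusted p of 0.958, and of 0.0475 without array 2 of Col-0. In the cell cycle list TOPII averaged 470 ± 66.1 against 626 ± 63.2, and AUR1, AUR2 and PRL had log2 differences of 0.02, -0.17 and 0.03. Photosynthesis genes differed little, with log2 differences of -0.04 for RCA, 0.03 for PSBY and -0.03 for PRK. The reference genes PEX4, AT2G28390 and AT4G34270 had log2 differences of -0.10, 0.01 and 0.00. The signs for AUR1, BAN and AT2G28390 turn with quantile normalization and with median centring. Heat shock, salicylate and meiosis lists had no tested member.

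Expansin genes were the one gene family with a camera call, and that call depends on the set test and on the correlation assumed between genes. The family search was a departure from the planned analysis, described in the processing summary. Camera with the preset correlation gave the 10 tested expansin and expansin-like genes an adjusted p of 0.00221 over 8 families, in the direction of higher signal in xrn4-5. The adjusted p was 0.503 with an estimated correlation, 0.190 with fry and 0.112 when dim probe sets were kept. Both xrn4-5 arrays lay above both Col-0 arrays in 7 of the 10 genes and below them in 0. Besides EXPA15, EXPB3 averaged 5228 ± 746 (SD, n = 2) in xrn4-5 against 3164 ± 560 in Col-0, and EXPA4 averaged 2191 ± 273 against 1647 ± 161. No expansin gene passed the limma test over all probe sets without a block, and the median log2 difference was 0.26. The remaining 7 families, among them those found by the patterns for RING finger, AP2/ERF and bZIP genes, had camera adjusted p-values from 0.405 to 0.995. Short patterns such as RING and ERF match anywhere in a name, so these groups may hold other genes.

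**Figure D2:**
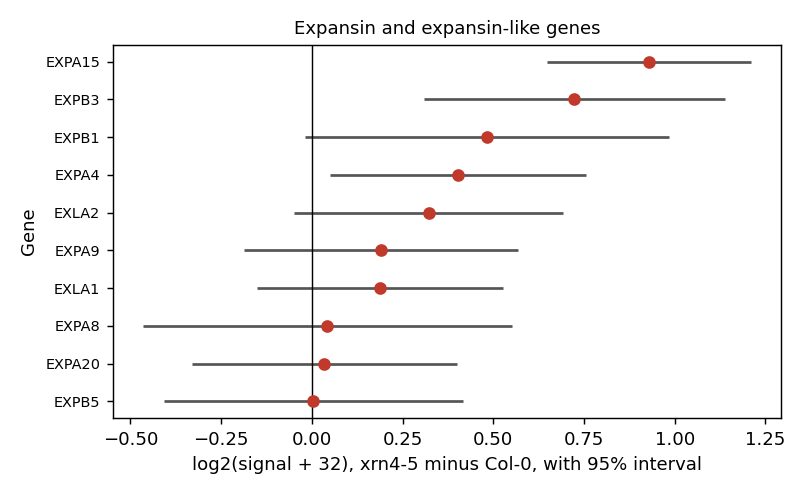
Difference between xrn4-5 and Col-0 in log2(signal + 32) for the 10 tested expansin and expansin-like genes, with 95% intervals from limma as lines. EXPA15 has the largest difference, 0.93, while that of EXPB5 is 0.00 and turns to -0.02 with quantile normalization or median centring.

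Control probe sets gave the signal along the actin, GAPDH and ubiquitin transcripts. Whether a difference between genotypes there reflects RNA quality or XRN4, which degrades uncapped RNA from its 5' end, was not tested. On the log2 scale the signal at the 5' end minus that at the 3' end of the actin control averaged -0.50 ± 0.03 (SD, n = 2) in xrn4-5 and -0.67 ± 0.01 in Col-0. The GAPDH control gave 0.10 ± 0.02 and 0.07 ± 0.03, and the ubiquitin control gave -0.19 ± 0.06 and -0.20 ± 0.03. With the older control design, the differences were -2.96 ± 0.11 and -2.95 ± 0.13 for actin, -0.46 ± 0.09 and -0.55 ± 0.09 for GAPDH, and -0.88 ± 0.04 and -0.81 ± 0.06 for ubiquitin. Middle probe sets of actin averaged 12717 ± 305 and 11160 ± 640 in the newer design and 6810 ± 189 and 5890 ± 335 in the older one. In the older design the middle probe sets of GAPDH averaged 8478 ± 634 and 8541 ± 207, and those of ubiquitin averaged 5508 ± 613 and 5903 ± 887. The probe set for 25S ribosomal RNA gave 274 and 251 in xrn4-5 against 763 and 296 in Col-0, with array 1 of Col-0 apart from the other 3.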

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

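AT3G49160 was the only gene among the probe sets too dim for the main test that met the less strict criterion with a mean log2(value + 32) higher by at least 2 in xrn4-5. On the linear scale other dim genes had folds as large. AT3G49160 gave 235 and 399 in xrn4-5 against 32.6 and 22.3 in Col-0, a log2 difference of 2.52 in a limma fit of all probe sets. In the authors' deposited table its log2 ratios were 2.2 and 3.6. No explanation was tested.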

How the results depend on the processing

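The tests with the authors' change p-value, on gene families, expansins included, and on other splits of the arrays were chosen after seeing the data; the rest were planned. Causes of the moves below were not tested, except that leaving out an array or probe sets leaves fewer of them. The single probe set called higher became 0 with no filter on dim probe sets, with eBayes without trend and with Welch's test, and ranged from 0 to 3 when an array was left out, where the lone array is assumed to vary like the others. The count called lower ranged from 0 to 8 in those fits. With the replicate block, 71 probe sets were called higher and 60 lower. These included the probe set of the main result, 48 of the 56 that met the less strict criterion and all 12 genes named for the smallest p. The labels do not say that a number marks a shared batch, and deviations of same-numbered arrays correlated at 0.42 over tested probe sets and 0.21 over all. Same-numbered arrays thus varied together in part, but with only 2 pairs and no such label, what they share is not known.

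Under the less strict criterion, the 25 higher and 31 lower probe sets became 16 and 18 with the higher pseudocount, 60 and 77 with no filter, and 6 and 3 with Welch's test. The 2-fold rule on the authors' deposited table gave 209 and 196, and 26 and 36 with its change p-value. These were counted over 22746 probe sets, dim ones included, and so are not counts among the 13647 tested. Of the 25 and 31 probe sets, 15 and 19 were also at least 2-fold in both pairs of that table. Leaving out an array gave 29 to 98 higher and 35 to 86 lower. The highest were 98 without Col-0 array 2 and 86 without Col-0 array 1. Lists called went from 0 to 1 with the replicate block (abscisic acid and dehydration, adjusted p = 0.0202) and ranged from 0 to 3 with an array left out. Those 3, without Col-0 array 2, had 3, 1 and 1 tested members. Expansins lost their call, and families called became 0, with no filter (adjusted p = 0.112), with fry (0.190) and with an estimated correlation (0.503). With the lowest 60% left out, families called were 0, as fewer than 10 expansin genes were tested. The other alternatives kept the expansin call, with adjusted p from 0.000392 (without Col-0 array 1) to 0.0341 (without EXPA15).

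Over the alternatives that keep all arrays, 416 of 437 values for 56 named genes kept direction and side of the threshold, 12 passed it (all with the replicate block) and 9 turned sign. Those were BAN (-0.021 with the higher pseudocount, -0.0044 with quantile normalization, -0.0022 with median centring) and, with quantile normalization and median centring in turn, AUR1 (-0.0042, -0.0080), AT2G28390 (-0.012, -0.019) and EXPB5 (-0.017, -0.021). With an array left out, 192 of 224 were the same and 32 turned sign. Their log2 differences ranged from -0.080 to 0.14 for PSBY, -0.84 to 0.88 for BAN, -0.42 to 0.085 for AUR2, -0.045 to 0.10 for PRL, -0.21 to 0.0031 for PEX4, -0.034 to 0.37 for AGO7, -0.25 to 0.072 for SE, -0.18 to 0.15 for JMT, -0.48 to 1.63 for COR15B, -0.15 to 0.061 for RCA, -0.18 to 0.11 for PRK, -0.088 to 0.12 for AUR1, -0.067 to 0.078 for AT2G28390, -0.054 to 0.044 for AT4G34270, -0.12 to 0.13 for EXPB5, -0.22 to 0.10 for AGL65, -0.26 to 0.36 for SPT, -0.11 to 0.52 for WES1, -0.59 to 0.35 for WRKY53, -0.41 to 0.00016 for AT5G07230 and -0.060 to 0.18 for AGL24. XRN4 has no value under any setting, because no probe set is named for it here, and the hexamer test and its alternatives were not run. Of the values of each array, 14.9% to 15.8% lay below the pseudocount, where differences are compressed.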

Other observations

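The tests on RNA integrity, harvest time and expansins were chosen after their results were seen, while those on iron genes were written before. Among genes with lower signal in xrn4-5 were 5 known to be induced by iron deficiency, picked after their values were seen and not tested for enrichment. BHLH101, a regulator of iron uptake that was too dim for the main test, gave 16.2 and 43.0 in xrn4-5 against 193 and 129 in Col-0. AT1G47400, which encodes a peptide of the IRONMAN family, PYE, AT5G05250 and AT3G56360 are also known to respond to low iron. The median log2 difference of these 5 genes was -1.66. SAPX, CCS and ARPN were also picked after their values were seen, so they are no independent evidence. SAPX, which is repressed under iron deficiency, was 2.37-fold higher and was the only measured gene of the 11 on its list. CCS and ARPN, both lowered under copper limitation, had log2 differences of -0.46 and -0.67. AT3G15640 of the same list, whose value had not been seen, had -0.04. None of these genes passed the adjusted limma test without a block. With the array number as a block, 19 of the 21 named genes that met the less strict criterion passed. AT1G47400, PYE, AT5G05250, AT3G56360 and SAPX are among the 21, but which of the 21 passed is not given here.

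A hypothesis from these values is that xrn4-5 inflorescences had a weaker iron deficiency response. The listed genes whose values had not been seen cannot decide it, since those that met the less strict criterion had been seen and set aside. Of 41 listed genes, only the 5 above and 6 others had a named probe set. Of these 6, 4 had higher and 2 lower estimates, with a median log2 difference of 0.07. Their median lay at percentile 67.3 of 10000 expression-matched random lists. That is the outcome predicted for selection of genes after seeing them, but the random lists were not filtered in this way. Only 3 of the 6 were bright enough for the main test. One aberrant array and a difference between same-numbered arrays stay open, because the 5 genes were picked for separated arrays. Such genes keep a low median when an array is left out (-1.42 or lower here) and must differ more between genotypes than between numbers, as all 5 did. Growth conditions and genotype remain untested.

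By both criteria array number separated more probe sets than genotype did, which points to a structure of the samples. Split by number, 5 probe sets passed limma and 114 met the less strict criterion, against 1 and 56 for genotype and 0 and 7 for the crossed split. At an unadjusted limma p under 0.05 the counts were 1129 by number, 1273 by genotype and 105 by the crossed split. PORB, a chlorophyll synthesis gene, gave 660 and 630 in the arrays numbered 1 and 2285 and 2509 in those numbered 2, and passed the test (limma adjusted p = 0.0205). COR15B, CCL and LTI30, picked from the genes that met the less strict criterion, also had higher signal in number 2 but missed the test (adjusted p from 0.119 to 0.243). Different RNA integrity is argued against for the control transcripts. The 5' minus 3' signal of actin, GAPDH and ubiquitin, each in 2 designs, shifted by a median of only -0.0062 and by -0.07 to 0.02. Harvest at another time of day may contribute and cannot be told apart, because GI, with a difference of 0.48, was the only clock gene measured. No biological explanation was tested.

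For the expansin genes, a trend of the difference with signal level is argued against, since their median lay at percentile 99.8 of 10000 expression-matched random lists. The split by number gave a camera p of 0.741, which decides nothing about a difference between same-numbered arrays, since each number occurs once per genotype. Whether these genes simply vary together from plant to plant stays open, and the loss of the call with an estimated correlation (adjusted p = 0.503) keeps it so. An effect of the genotype may exist but is untested beyond these 4 arrays.

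In the authors' deposited table, 18 probe sets not tested here differed at least 2-fold in both pairs with a change p-value under 0.01 or over 0.99. Among them, picked after their values were seen, were AT3G43670, with 80.4 and 147 in xrn4-5 against 7.30 and 11.7 in Col-0, and AT1G12030, with 11.2 and 4.50 against 238 and 104.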
